A study of Arabidopsis thaliana with 8 samples.

How the data were processed

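Whole seedlings of Arabidopsis thaliana, 7 days old and kept in 24 h light per the labels, were sequenced as 100-base paired-end RNA libraries after extraction with an RNeasy plant kit. The design text breaks off in the middle of the growth medium, so the medium is not used here. Each of the 4 genotypes had 2 libraries, and groups and replicate numbers were taken from the sample titles and genotype labels.

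The authors deposited a workbook with whole-number counts per gene for each library, per the file headers: total gene reads, unique gene reads, exon reads and intron reads. Aligner, counter, strand setting and genome build are not given in the sources used here. The deposited RPKM values equalled exon reads over exon length and library total within 0.1% for 100% of genes in each library, and were used only for that check. The authors' second sheet holds a signed fold, used here as a score with no fixed range, of the double mutant against cob-6, deposited with the p-value of an EDGE test with tagwise dispersions, per the file headers. A last sheet lists genes that the authors describe as changed in cob-6 and not in the double mutant, without stated criteria. The workbook held 0 columns of samples of other series.

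Gene positions are those of the deposited table, and symbols were matched to the reference annotation by locus identifier. Of 33602 genes, 32813 overlapped the locus of the same name, 10599 with the same start and end, 779 were not in the reference table, and 10 overlapped another place, so no reference coordinate is printed. All 418 genes of the fixed lists were found in the table. Genes whose reads were mostly shared with a copy or an overlapping gene are named as such, because the use of strand in counting is not given.

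The main test was edgeR's quasi-likelihood test on total gene reads, with TMM scaling (CPM are reads scaled to the library total), genes kept by filterByExpr, 1 mean per genotype and 4 residual degrees of freedom shared over all 8 libraries. It covered 21384 genes in 6 contrasts, the last being the interaction, that is the change from sfr6-3 to the double mutant minus the change from WT to cob-6. Every adjusted p named for a gene is that test's p after Benjamini-Hochberg adjustment over all tested genes of the contrast, with a call at 0.05. Changes are log2 fold changes with standard errors. The prior degrees of freedom were 7.91 and the biological coefficient of variation 0.214.

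In all, 23 gene lists were tested with camera from limma, with a preset correlation of 0.01 between genes and log2 CPM with a prior count of 2, adjusted over all lists and the 6 contrasts. Camera with an estimated correlation and fry were run beside it. The preset test called 33 combinations of list and contrast, and 0 held with an estimated correlation. The lowest adjusted p of fry was 0.234 in its test for a change one way on balance. In its test for changes in either direction it was 6.62e-05, for salicylic acid defence in sfr6-3 against WT and in the double mutant against cob-6. Counts "adjusted over the list alone" used Benjamini-Hochberg within the list. The groups, contrasts, lists, tests and other settings were fixed before the data were examined.

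Genes were named by a rule fixed with them: COB and MED16 always, then in each contrast the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries compared, where they have a symbol, and up to 4 members with the smallest p of each list with 2 or more calls or a camera call. For the interaction the condition on overlap was not used. A contrast with no call would have given its 3 smallest p-values. Genes outside the rule are said to have been chosen after their values were seen, except the overlapping genes and families weighed in the closing part and the genes with the smallest p in the authors' table.

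The test was tested on simulated counts with the means and depths of these libraries. For cob-6 against WT, 46 of 100 genes changed 2-fold and 80 of 100 changed 4-fold were recovered among 21384 genes, with 9 false calls. The simulated libraries were drawn independently, whereas WT replicate 1 held at least the summed unique reads of the others. The recovery therefore does not carry over to contrasts with WT. For the double mutant against sfr6-3, 59 of 100 and 80 of 100 were recovered, with 22 false calls. In the single draw made for each contrast, false calls thus made up more than the nominal 0.05 of all calls. Each gene was simulated with the same dispersion in every genotype, whereas the double mutant replicates correlated least, at r = 0.934. The recovery for the double mutant against sfr6-3 may therefore not carry over either. A simulated list of 17 genes changed 2-fold in cob-6 against WT gave p = 3.49e-23 with the preset correlation in an edgeR and limma fit, and p = 0.000433 with an estimated one. Its genes were drawn at random and simulated without correlation between them. It therefore does not test the preset on lists of co-regulated genes.

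The other settings fixed with the design were DESeq2, its size factors in edgeR, no filter on low counts, only the libraries compared, the replicate number as a block, each library left out in turn, a test against a 1.5-fold change and unique reads. After the data were seen, exon reads and unique reads with the sum of the other 7 libraries taken off WT replicate 1 were added. The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

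Depth ran from 24011199 to 324504432 gene reads, of which 94.2 to 95.3% were unique and 0.456 to 0.69% came from the chloroplast genome. TMM factors ran from 0.94 to 1.05. The detection floor given per library is that of 3 reads.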

Results

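RNA of whole Arabidopsis seedlings was sequenced in 4 genotypes with 2 libraries each: the Columbia wild type (WT), cob-6, sfr6-3 and the double mutant cob-6sfr6-3. The cob-6 allele lies in COB, which encodes a membrane-anchored wall protein needed for oriented cellulose deposition, and sfr6-3 lies in MED16, which encodes a tail subunit of the Mediator complex. The series title names MED16 as the gene of a COBRA suppressor. The comparisons therefore asked what each allele changed alone, what sfr6-3 changed in cob-6, and whether the effects of the alleles added up.

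The library labelled WT replicate 1 held 324504432 gene reads and WT replicate 2 held 26218809. The cob-6 libraries held 25195271 and 24011199 gene reads, the sfr6-3 libraries 24437892 and 26610332, and the double mutant libraries 26271183 and 37744914. A gene with 3 reads stood at 0.00924 CPM in WT replicate 1 and at 0.0795 to 0.125 CPM in the other 7 libraries, which covers counting error only. Replicates correlated across genes, which are not independent replicates, at r = 0.975 in WT, 0.973 in cob-6, 0.965 in sfr6-3 and 0.934 in the double mutant, on log2 CPM. The first principal component took 29.8% of the variance and set double mutant replicate 2 apart at 100.5, while the second took 19.9% and set double mutant replicate 1 apart at -81.8. The counts of each replicate pair differed by more than sampling noise in a chi-square test, so no library was counted as a copy of its replicate. That test grows with depth and was not used to compare genotypes. The labels do not say whether replicates were grown separately, so p-values measure only the spread between these samples, which may be technical.

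The library labelled WT replicate 1 was not independent of the others in its counts. In uniquely assigned reads, 0 of 25179 genes had fewer reads in WT replicate 1 than in the other 7 libraries together, and 1178 genes had exactly their sum. A simulated library of the same depth with the profile of WT replicate 2 fell below that sum for 3960 of 24551 genes, and one with the mean profile of the other 7 libraries did so for 230, with 290 exactly equal. Of 15 genes read almost only in double mutant replicate 2, 15 were also read in WT replicate 1, at a median of 0.127 of their CPM. WT replicate 1 lay closer to the cob-6 libraries, at a median absolute deviation of 0.257 and 0.252 in log2 CPM, than to WT replicate 2, at 0.33. The same held for the sfr6-3 libraries, at 0.269 and 0.29, and for double mutant replicate 1, at 0.322. Double mutant replicate 2 lay farther away, at 0.42. If WT replicate 1 held reads of the mutants, planned changes against WT would be understated. The p-values of contrasts with WT also assume independent libraries. Comparisons with WT are therefore given with all 8 libraries, as planned. Counts of calls, and values of some genes and lists, are also given without WT replicate 1 or with the summed unique reads of the other 7 libraries taken off it. Both of the latter are set beside the planned counts because they moved them by more than 1.5 times. The subtracted WT replicate 1 still had the most unique reads of all libraries. It deviated by 0.322 and 0.315 from the cob-6 libraries, and by 0.356 from WT replicate 2. From the sfr6-3 libraries it deviated by 0.336 and 0.348, and from the double mutant by 0.384 and 0.493. Its spread around the mean of the others was 0.232, where theirs ran from 0.266 to 0.465. It is thus not shown to be an ordinary wild-type library.

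**Figure D1:**
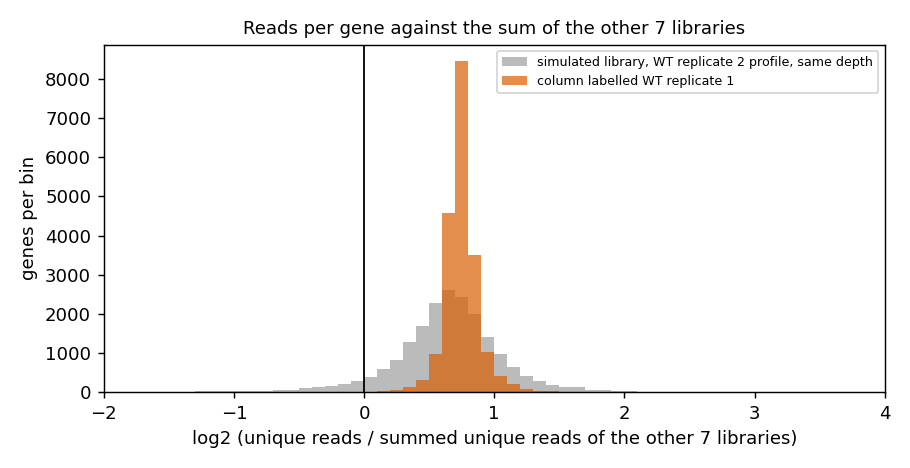
Histogram of genes by the log2 ratio of unique reads in the library labelled WT replicate 1 to the summed unique reads of the other 7 libraries, in bins of 0.1, for 19871 genes with at least 100 unique reads in the other 7, beside a simulated library of the same depth with the profile of WT replicate 2. In WT replicate 1, 0 genes lay below the sum, against 1330 in the simulated library.

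COB (AT5G60920, chromosome 5, 24511196 to 24514129) was lower in both genotypes that carry cob-6. It stood at 143 and 225 CPM in WT, 70.6 and 67.9 CPM in cob-6, 196 and 187 CPM in sfr6-3, and 80.8 and 69.3 CPM in the double mutant. MED16 (AT4G04920, chromosome 4, 2497644 to 2505535) was lower in both genotypes that carry sfr6-3, at 24.2 and 32.5 CPM in WT, 30.3 and 39.7 CPM in cob-6, 9.0 and 8.49 CPM in sfr6-3, and 10.6 and 7.37 CPM in the double mutant. Coordinates are those of the deposited table, whose genome build is not given in the sources used here. Both genes were read at 100% by reads unique to them. The target genes thus matched the labels of the other 7 libraries. In WT replicate 1, COB lay between WT replicate 2 and the cob-6 libraries, and MED16 between WT replicate 2 and the sfr6-3 libraries. The raw levels therefore do not settle the label of WT replicate 1. After the reads of the other 7 libraries were taken off, WT replicate 1 held 178 CPM of COB in unique reads, beside 238 in WT replicate 2. For MED16 these values were 33.7 and 34.5 CPM.

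**Figure D2:**
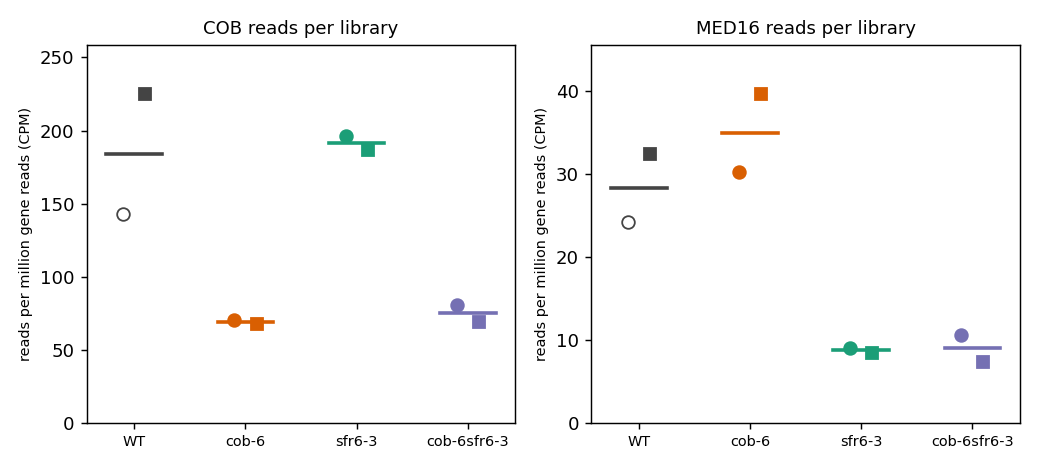
CPM of COB and MED16, scaled to total gene reads, in each library of the 4 genotypes, with circles for replicate 1, squares for replicate 2, an open circle for the library labelled WT replicate 1, and lines for the mean of 2 libraries. COB lay between 67.9 and 80.8 CPM in the 4 libraries with cob-6, and MED16 between 7.37 and 10.6 CPM in the 4 libraries with sfr6-3.

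The comparison of cob-6 with WT gave the effect of cob-6 alone. COB fell by 1.5 ± 0.21 on the log2 scale (SE, n = 2 libraries per genotype unless a library is left out, adjusted p = 0.0251). It stood at -1.82 without WT replicate 1 and at -1.08 without WT replicate 2. AGP30, a root arabinogalactan protein gene, fell by 2.58 ± 0.40 (adjusted p = 0.0354), and the peroxidase gene PER23 fell by 1.98 ± 0.22 (adjusted p = 0.00444). MLP328 fell by 2.21 ± 0.34 (adjusted p = 0.0354). MRD1 fell by 5.33 ± 0.57 (adjusted p = 0.00425) and its overlapping neighbour HEI10, known for its role in meiotic crossovers, fell by 2.63 ± 0.29 (adjusted p = 0.00444). Only 13.7% of MRD1 reads and 23.1% of HEI10 reads were unique to them, and in unique reads neither was called, with MRD1 at -3.36 ± 0.59 (adjusted p = 0.0603) and HEI10 at -0.82 ± 0.47 (adjusted p = 0.999). MED16 gave 0.23 ± 0.23 (adjusted p = 0.999).

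Root hair genes stood higher in cob-6 as a group. Of 17 tested, 0 rose over all genes in edgeR, 11 were higher at an unadjusted p below 0.05, DESeq2 called 6, and 11 rose adjusted over the list alone, with a median log2 change of 1.03 (camera adjusted p = 8.24e-12, higher, and adjusted p = 0.681 with an estimated correlation). RHS13, a gene of root hair cells, gave 1.03 ± 0.23 (adjusted p = 0.258) and the root hair wall protein gene PRP3 gave 1.18 ± 0.28 (adjusted p = 0.301). Without WT replicate 1, RHS13 stood at 1.46 and PRP3 at 1.72, with WT replicate 2 alone as the wild type. The mean centred log2 CPM of the list was 0.1 and -0.45 in WT and 0.8 and 0.78 in cob-6. Beside them, the 20 root markers had a median of -0.40 (0 called in edgeR, 0 higher and 7 lower at unadjusted p below 0.05, 1 by DESeq2, 3 fell adjusted over the list alone, camera adjusted p = 3.37e-06, lower, and adjusted p = 0.681 with an estimated correlation). CASP1, which scaffolds the Casparian strip, gave -0.89 ± 0.20 (adjusted p = 0.258).

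Jasmonate genes also stood higher in cob-6. Among 16 tested genes of jasmonate synthesis and its MYC branch, 0 rose over all genes in edgeR and 0 by DESeq2, 7 were higher at unadjusted p below 0.05, and 6 rose adjusted over the list alone, with a median of 0.82 (camera adjusted p = 5.91e-06, and adjusted p = 0.681 with an estimated correlation). LOX2, which makes a jasmonate precursor, gave 1.58 ± 0.49 (adjusted p = 0.572), and CORI3 gave 1.76 ± 0.47 (adjusted p = 0.435). CORI3 stood at 2.58 without WT replicate 1, with WT replicate 2 alone as the wild type. The mean centred log2 CPM of the jasmonate list was 0.07 in WT replicate 1 and -0.8 in WT replicate 2, the lowest of all libraries. Of 17 glucosinolate genes, 0 rose over all genes in edgeR, 7 were higher at unadjusted p below 0.05, 1 by DESeq2, and 3 rose adjusted over the list alone, at a median of 0.43 (camera adjusted p = 2.21e-05, and adjusted p = 0.698 with an estimated correlation). MAM3, of side-chain elongation in glucosinolate synthesis, gave 1.14 ± 0.19 (adjusted p = 0.0508).

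Photosynthesis and secondary wall genes stood lower in cob-6. Of 18 green tissue markers, 0 fell over all genes in edgeR, 5 were lower at unadjusted p below 0.05, 3 by DESeq2, and 3 fell adjusted over the list alone, at a median of -0.28 (camera adjusted p = 9.48e-05, and adjusted p = 0.853 with an estimated correlation). The light-harvesting gene LHCB1.1 gave -1.03 ± 0.25 (adjusted p = 0.315). The mean centred log2 CPM of the green list was 0.1 and 0.27 in WT and -0.32 and 0.01 in cob-6. Of 25 secondary wall and xylem genes, 0 fell over all genes in edgeR, 4 were lower at unadjusted p below 0.05, 0 by DESeq2, and 0 adjusted over the list alone, at a median of -0.30 (camera adjusted p = 0.000211, and adjusted p = 0.681 with an estimated correlation), which was -0.14 with WT replicate 1 less the other 7. The xylan synthesis gene FRA8 gave -0.75 ± 0.20 (adjusted p = 0.417). The 21 iron deficiency genes had a median of 0.36 (0 called in edgeR and 0 by DESeq2, 3 higher and 1 lower at unadjusted p below 0.05, camera adjusted p = 0.0108, higher, and adjusted p = 0.884 with an estimated correlation). The iron median was 0.89 without WT replicate 1 and 1.19 with WT replicate 1 less the other 7. FIT, the transcription factor of iron uptake, fell adjusted over the list alone, at -0.74 ± 0.18. The iron list did not keep to genotype, at 0.03 and -1.23 in the WT libraries and -0.68 and 0.63 in the cob-6 libraries.

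In all, 19 genes were called in cob-6 against WT, 0 higher and 19 lower, among 21384 tested. At an unadjusted p below 0.05 there were 1125, and DESeq2 called 129. Without WT replicate 1 the count was 138, of which 40 were higher and 98 lower and which held all 19, and with WT replicate 1 less the other 7 it was 88. Without WT replicate 2 it was 24, with 10 higher and 14 lower, of which 11 were among the planned 19. Without cob-6 replicate 1 or cob-6 replicate 2 it was 0 each time, with 704 and 722 at unadjusted p, and COB then stood at -1.51 and -1.48.

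The comparison of sfr6-3 with WT gave the effect of the MED16 allele alone. MED16 fell by 1.78 ± 0.24 (adjusted p = 0.0226) and COB gave -0.03 ± 0.20 (adjusted p = 0.998). RD29A, a cold and dehydration response gene, fell by 2.36 ± 0.36 (adjusted p = 0.0382), and so did the extensin gene EXT1 at -2.28 ± 0.20 (adjusted p = 0.00113), the lipase gene PLP2 at -3.44 ± 0.50 (adjusted p = 0.0285) and the myrosinase gene TGG2 at -1.5 ± 0.24 (adjusted p = 0.0414). The ammonium transporter gene AMT1-3 rose by 1.02 ± 0.15 (adjusted p = 0.0285) and ILA by 0.91 ± 0.15 (adjusted p = 0.0499). EXLB1, an expansin-like gene chosen after its values were seen, fell by 2.53 ± 0.32 (adjusted p = 0.0179).

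Cold-regulated genes stood lower in sfr6-3. Of 16 tested, 1 (RD29A) fell over all genes and 6 fell adjusted over the list alone, at a median of -0.70 (camera adjusted p = 1.5e-05, and adjusted p = 0.681 with an estimated correlation). COR413IM1 gave -2.84 ± 0.51 (adjusted p = 0.0828), the dehydrin gene LTI30 -1.62 ± 0.30 (adjusted p = 0.0833) and KIN2 -2.74 ± 0.51 (adjusted p = 0.0912). COR413IM1 stood at -3.45 without WT replicate 1, with WT replicate 2 alone as the wild type. The mean centred log2 CPM of the cold list was 0.29 and 0.4 in WT and -0.83 and -0.69 in sfr6-3. Flavonoid genes pointed the same way, with 13 of 13 negative and a median of -0.95 (0 called in edgeR, 4 lower at unadjusted p below 0.05, 2 by DESeq2, 4 fell adjusted over the list alone, camera adjusted p = 1.03e-05, and adjusted p = 0.681 with an estimated correlation). CHS, the entry enzyme of flavonoid synthesis, gave -1.11 ± 0.28 (adjusted p = 0.299).

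Among the wall lists, xyloglucan, glycoprotein and pectin genes stood lower in sfr6-3 and secondary wall genes stood higher, each by small amounts. Among 33 xyloglucan genes 0 were called in edgeR, 1 was higher and 10 lower at unadjusted p below 0.05, 1 was called by DESeq2, and 0 were called adjusted over the list alone, at a median of -0.30 (camera adjusted p = 0.00223, and adjusted p = 0.681 with an estimated correlation). Of 18 wall glycoprotein genes 1 fell (EXT1) and 3 fell adjusted over the list alone, at a median of -0.20 (camera adjusted p = 0.0144, and adjusted p = 0.853 with an estimated correlation). Of 24 pectin genes 0 fell in edgeR, 5 were lower at unadjusted p below 0.05, 1 by DESeq2, and 2 fell adjusted over the list alone, at a median of -0.15 (camera adjusted p = 0.047, and adjusted p = 0.681 with an estimated correlation). The camera adjusted p of the pectin genes was 0.0559 without WT replicate 1, 0.102 without double mutant replicate 1 and 0.0868 without double mutant replicate 2. The 25 secondary wall genes stood at a median of 0.17 (0 called in edgeR, 1 higher at unadjusted p below 0.05, 1 by DESeq2, 1 rose adjusted over the list alone, camera adjusted p = 0.0119, higher, and adjusted p = 0.681 with an estimated correlation), led by the xylem peptidase gene XCP2 at 0.71 ± 0.15 (adjusted p = 0.126), and their camera adjusted p was 0.139 without WT replicate 1.

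Among 4 tested genes of the jasmonate and ethylene defence branch, 0 fell in edgeR, 2 were lower at unadjusted p below 0.05, 1 by DESeq2, and 2 fell adjusted over the list alone, at a median of -1.74 (camera adjusted p = 0.0108, and adjusted p = 0.681 with an estimated correlation). PR4, a chitin-binding defence protein gene, gave -1.41 ± 0.27 (adjusted p = 0.107). Of 17 glucosinolate genes 1 fell (TGG2), also adjusted over the list alone, at a median of -0.20 (camera adjusted p = 0.0341, and adjusted p = 0.864 with an estimated correlation). The 17 root hair genes had a median of -0.45 (0 called in edgeR, 4 lower at unadjusted p below 0.05, 1 by DESeq2, 4 fell adjusted over the list alone, camera adjusted p = 0.0052, and adjusted p = 0.833 with an estimated correlation). The 21 iron genes had a median of 0.44 (0 called in edgeR and 0 by DESeq2, 2 higher and 1 lower at unadjusted p below 0.05, 1 rose adjusted over the list alone, camera adjusted p = 0.00217, higher, and adjusted p = 0.864 with an estimated correlation), with FIT at 0.70 ± 0.17 (adjusted p = 0.294). The mean centred log2 CPM of the iron list was -0.06 and 0.07 in sfr6-3, on either side of 0.03 in WT replicate 1 and above -1.23 in WT replicate 2. Green tissue markers stood at a median of -0.28 (0 called in edgeR and 0 by DESeq2, 3 lower at unadjusted p below 0.05, 0 adjusted over the list alone, camera adjusted p = 0.00738, and adjusted p = 0.864 with an estimated correlation). Their mean centred log2 CPM overlapped between the genotypes, at 0.1 and 0.27 in WT and -0.19 and 0.12 in sfr6-3. The 17 cell division genes stood at 0.25 (0 called in edgeR, 0 by DESeq2, 0 at unadjusted p below 0.05 and 0 adjusted over the list alone, camera adjusted p = 0.0376, and adjusted p = 0.864 with an estimated correlation). Leaving out WT replicate 1 gave the root hair genes a median of 0 (camera adjusted p = 0.686), the glucosinolate genes -0.03 (0.5), the defence branch -1.73 (0.0516) and the cell division genes 0.46 (0.00627), and with WT replicate 1 less the other 7 the iron median was 0.73. Without double mutant replicate 1 or 2 it was 0.0867 or 0.0767 for the glucosinolate genes and 0.0634 or 0.0625 for the cell division genes, which stood at 0.165 with WT replicate 1 less the other 7. Lists without a planned call also passed with a library left out, all lower: without WT replicate 1 the camera adjusted p was 0.0242 for primary-wall cellulose synthesis, 0.035 for the circadian clock and 0.0449 for abscisic acid and dehydration, and it was 0.00898 for the last without double mutant replicate 1.

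In all, 28 genes were called in sfr6-3 against WT, 2 higher and 26 lower, with 1195 at an unadjusted p below 0.05 and 174 by DESeq2. Without WT replicate 1 the count was 168, of which 17 were higher and 151 lower and which held 27 of the 28, and with WT replicate 1 less the other 7 it was 151. Without WT replicate 2 it was again 28, but with 11 higher and 17 lower, and only 13 of them were among the planned 28. Without sfr6-3 replicate 1 or sfr6-3 replicate 2 it was 3, with MED16 at -1.79 (adjusted p = 0.189) and -1.76 (adjusted p = 0.258), and without double mutant replicate 2 it was 50.

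The comparison of the double mutant with cob-6 gave what the MED16 allele changed in cob-6, the background in which the title names it a suppressor. MED16 fell by 1.91 ± 0.24 (adjusted p = 0.00341) and COB gave 0.18 ± 0.20 (adjusted p = 0.712). ICL, which encodes isocitrate lyase of the glyoxylate cycle, rose by 2.41 ± 0.24 (adjusted p = 0.000768). MRD1 rose by 5.23 ± 0.57 (adjusted p = 0.00129) and HEI10 by 3.51 ± 0.30 (adjusted p = 0.000274), on 13.7% and 23.1% unique reads. In unique reads alone MRD1 rose by 3.48 ± 0.59 (adjusted p = 0.0116) and HEI10 gave 1.98 ± 0.47 (adjusted p = 0.0558). ACT fell by 5.21 ± 0.96 (adjusted p = 0.0248) and EXLB1, chosen after its values were seen, fell by 3.18 ± 0.33 (adjusted p = 0.000999). ABCI4 was called at 2.54 ± 0.51 (adjusted p = 0.0361) in gene reads and stood at -0.01 in exon reads.

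Single cold, flavonoid and glucosinolate genes fell in the double mutant against cob-6, and most other members of these lists had negative values that did not pass the test. Of 16 cold genes 4 fell over all genes and 6 adjusted over the list alone, at a median of -0.65 (camera adjusted p = 0.00368, and adjusted p = 0.681 with an estimated correlation), among them COR413IM1 at -3.92 ± 0.55 (adjusted p = 0.00588), RD29A at -3.59 ± 0.38 (adjusted p = 0.000999) and KIN2 at -2.88 ± 0.49 (adjusted p = 0.0185). Of 13 flavonoid genes 3 fell and 7 fell adjusted over the list alone, at a median of -1.29 (camera adjusted p = 3.8e-05, and adjusted p = 0.698 with an estimated correlation). CHS fell by 1.93 ± 0.29 (adjusted p = 0.00821), FLS1 fell by 1.17 ± 0.25 (adjusted p = 0.0434) and F3H fell by 1.87 ± 0.27 (adjusted p = 0.00691), the last with 12.9% unique reads, in which it gave -1.62 ± 0.53 (adjusted p = 0.15). The mean centred log2 CPM of the flavonoid list was -0.24 and -1.37 in the double mutant beside 0.7 and 0.74 in cob-6, and the median was -1.99 without double mutant replicate 1. Of 17 glucosinolate genes 3 fell and 6 fell adjusted over the list alone, at a median of -0.39 (camera adjusted p = 0.0108, and adjusted p = 0.864 with an estimated correlation), with TGG2 at -2.47 ± 0.25 (adjusted p = 0.000795). Without double mutant replicate 2, CHS stood at -1.87 (adjusted p = 0.0635) and F3H at -1.68 (adjusted p = 0.0585), and the camera adjusted p of the glucosinolate genes was 0.0868. Without double mutant replicate 1 it was 0.0592 for the glucosinolate genes and 0.0712 for the cold genes. The green tissue markers stood at a median of 0.17 (camera adjusted p = 0.252).

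Defence and pectin genes included single falls without a call for their lists. Of the 4 jasmonate and ethylene defence genes 2 fell (median -0.8, camera adjusted p = 0.287), namely PR4 at -1.85 ± 0.28 (adjusted p = 0.00821) and ORA59, a transcription factor of that branch, at -4.05 ± 0.72 (adjusted p = 0.0216). Of the pectin genes 3 fell and 5 fell adjusted over the list alone (camera adjusted p = 0.297). These were PGIP1 and PGIP2, which encode inhibitors of polygalacturonase, with PGIP2 at -1.06 ± 0.19 (adjusted p = 0.0232), and the pectin methylesterase gene PME17 at -0.98 ± 0.21 (adjusted p = 0.0471). PGIP1 overlaps another gene and had 10.6% unique reads, in which it fell by 1.9 ± 0.3 (adjusted p = 0.00913). The median of the 4 defence genes rested on single libraries, at -2.71 without double mutant replicate 2 (camera adjusted p = 0.0256) and -0.49 without replicate 1 (camera adjusted p = 0.785). The xyloglucan list, at a camera adjusted p of 0.0584, passed without WT replicate 1 at 0.0206, lower.

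The 17 root hair genes had a median of -0.76 against cob-6 (0 called in edgeR, 8 lower at unadjusted p below 0.05, 5 by DESeq2, 5 fell adjusted over the list alone, camera adjusted p = 3.8e-05, and adjusted p = 0.681 with an estimated correlation), with RHS19 at -1.04 ± 0.24 (adjusted p = 0.0608). The iron list gave 1 rise and 1 fall, and 6 rises and 2 falls adjusted over the list alone, at a median of 0.64 (camera adjusted p = 0.0539). Without WT replicate 1, 5 iron genes rose and the camera adjusted p was 0.0213, and with WT replicate 1 less the other 7 these were 5 and 0.0151. FIT rose by 1.14 ± 0.18 (adjusted p = 0.0118) and CYP82C4, of coumarin synthesis, fell by 1.58 ± 0.34 (adjusted p = 0.048). Among 20 root markers 1 rose, the phosphate transporter gene PHT1;1 at 0.88 ± 0.18 (adjusted p = 0.0392), and 4 adjusted over the list alone, at a median of 0.37 (camera adjusted p = 0.00738, and adjusted p = 0.681 with an estimated correlation). The 25 secondary wall genes had a median of 0.42 (0 called in edgeR, 5 higher at unadjusted p below 0.05, 1 by DESeq2, 0 adjusted over the list alone, camera adjusted p = 0.00598, higher, and adjusted p = 0.681 with an estimated correlation). The root marker value was 0.133 without double mutant replicate 2.

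In all, 291 genes were called in the double mutant against cob-6, 100 higher and 191 lower, with 1010 by DESeq2. Without cob-6 replicate 1 or replicate 2 the count was 68 or 78. It was 933 without double mutant replicate 1 and 121 without double mutant replicate 2. Of the 291 genes, 30 were read mostly by shared reads.

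The comparison of the double mutant with WT gave the joint effect of both alleles, including any interaction between them. COB fell by 1.32 ± 0.21 (adjusted p = 0.0124) and MED16 fell by 1.68 ± 0.24 (adjusted p = 0.00829). ICL rose by 1.70 ± 0.23 (adjusted p = 0.00626), BCB, which encodes a blue copper-binding protein, by 0.96 ± 0.18 (adjusted p = 0.0276) and GMI1 by 1.34 ± 0.26 (adjusted p = 0.0377). Without WT replicate 1, COB stood at -1.64, MED16 at -1.92 and ICL at 2.17. Without WT replicate 2 these values were -0.91, -1.41 and 1.37. TIP2-3, a tonoplast aquaporin gene, fell by 4.72 ± 0.61 (adjusted p = 0.00527), NEET, of iron-sulphur clusters, fell by 3.87 ± 0.49 (adjusted p = 0.00516) and UMAMIT17 fell by 3.30 ± 0.37 (adjusted p = 0.0039). EXLB1 and the clock-related transcription factor gene RVE1, both chosen after their values were seen, were called at -3.04 ± 0.33 (adjusted p = 0.00347) and -1.56 ± 0.25 (adjusted p = 0.0146).

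Single cold and flavonoid genes fell in the double mutant against WT, and the iron list stood higher. Of 13 flavonoid genes 2 fell and 6 fell adjusted over the list alone, at a median of -1.251 (camera adjusted p = 2.24e-05, and adjusted p = 0.688 with an estimated correlation). CHS fell by 1.90 ± 0.29 (adjusted p = 0.0107). The flavonoid median was -1.96 without double mutant replicate 1. Of 16 cold genes 3 fell and 6 fell adjusted over the list alone, at a median of -0.50 (camera adjusted p = 0.0333, and adjusted p = 0.833 with an estimated correlation), with COR413IM1 at -3.96 ± 0.55 (adjusted p = 0.0071). Of the 16 cold genes 9 were negative and 7 positive, and the mean centred log2 CPM of the list was 0.29 and 0.4 in WT and -0.74 and 0.02 in the double mutant. The camera adjusted p of the cold genes was 0.136 with WT replicate 1 less the other 7 and 0.268 without double mutant replicate 1. Of 21 iron genes 0 rose over all genes in edgeR, 14 were higher and 1 lower at unadjusted p below 0.05, 3 by DESeq2, and 12 rose adjusted over the list alone, at a median of 0.93 (camera adjusted p = 0.000103, and adjusted p = 0.864 with an estimated correlation). Of them, 9 rose over all genes without WT replicate 1. The mean centred log2 CPM of the iron list was 0.03 and -1.23 in WT and 0.69 and 0.55 in the double mutant. The count without WT replicate 1 thus rests on WT replicate 2, the lowest of all libraries for this list. PYE, a transcription factor of the iron response, gave 0.93 ± 0.25 (adjusted p = 0.127), and FRO3, a ferric reductase gene, 0.98 ± 0.25 (adjusted p = 0.0986).

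Single wall genes fell in the double mutant against WT. Of the 33 xyloglucan genes 2 fell and 4 fell adjusted over the list alone (camera adjusted p = 0.252), namely the xyloglucan endotransglucosylase genes XTH15 at -2.52 ± 0.40 (adjusted p = 0.0138) and XTH22 at -2.24 ± 0.43 (adjusted p = 0.0337). The 12 genes of primary-wall cellulose synthesis had a median of -0.30 (0 called in edgeR, 4 lower at unadjusted p below 0.05, 0 by DESeq2, 0 adjusted over the list alone, camera adjusted p = 0.0272, and adjusted p = 0.864 with an estimated correlation). The cellulose synthase genes CESA1 and CESA3 gave -0.44 ± 0.18 and -0.42 ± 0.18. The 16 jasmonate genes had a median of 0.54 (0 called in edgeR, 4 higher at unadjusted p below 0.05, 1 by DESeq2, 1 rose adjusted over the list alone, camera adjusted p = 0.021, and adjusted p = 0.864 with an estimated correlation). The green tissue and root markers stood at medians of -0.11 (camera adjusted p = 0.215) and 0.03 (camera adjusted p = 0.902). The cellulose value was 0.321 without double mutant replicate 2, and the jasmonate value 0.251 without double mutant replicate 1. The jasmonate median was 0.94 without WT replicate 1. The 17 root hair genes stood at 0.24 (camera adjusted p = 0.375), and without WT replicate 1 at 0.61 (camera adjusted p = 0.0213), where 2 rose. The 4 defence genes stood at -0.87 (camera adjusted p = 0.0584), at -1.86 without double mutant replicate 2 (camera adjusted p = 0.00254) and, with 3 tested, at -1.53 with WT replicate 1 less the other 7 (camera adjusted p = 0.0258).

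In all, 181 genes were called in the double mutant against WT, 10 higher and 171 lower, with 736 by DESeq2. Without WT replicate 1 the count was 767, of which 241 were higher and 526 lower and which held all 181, and with WT replicate 1 less the other 7 it was 748. It was 75 without WT replicate 2 and 76 without double mutant replicate 2, where COB stood at -1.21 (adjusted p = 0.103) and MED16 at -1.43 (adjusted p = 0.0525).

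**Figure D3:**
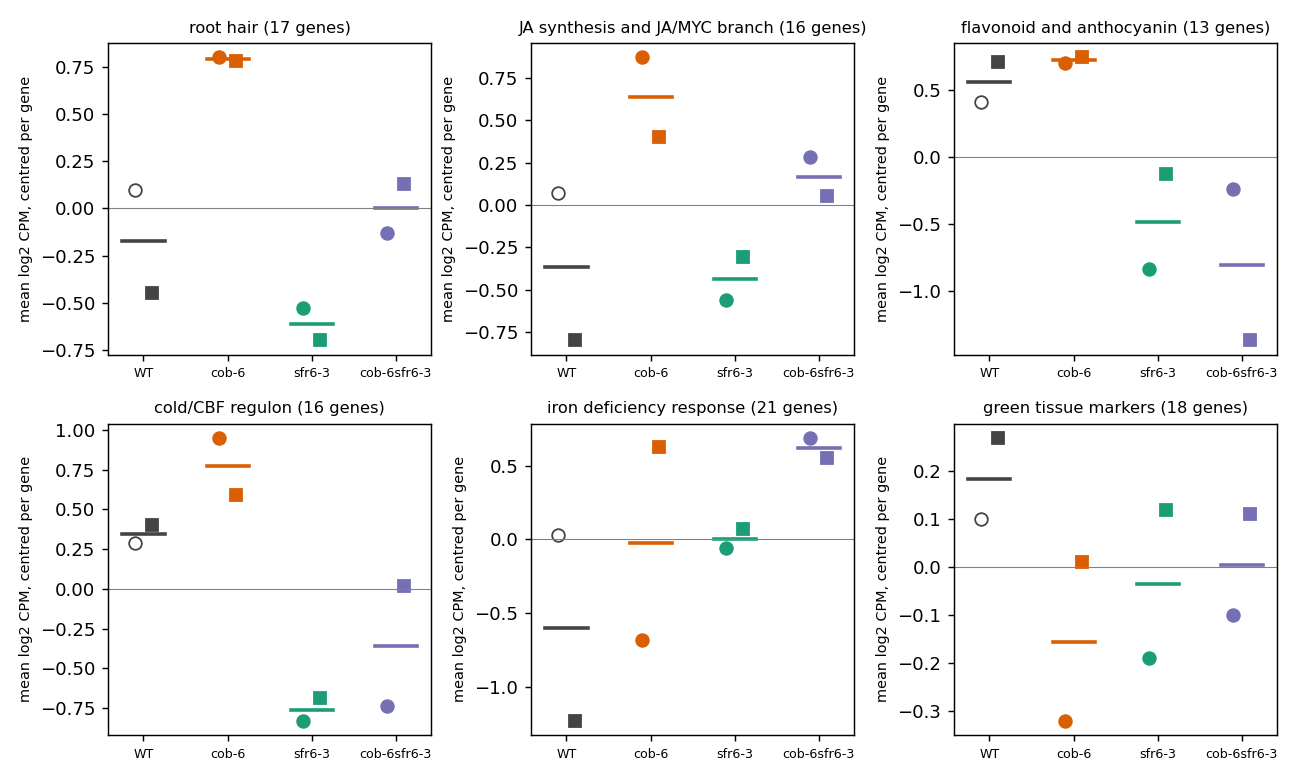
Mean centred log2 CPM per library of the root hair (17 genes), jasmonate (16), flavonoid (13), cold (16), iron (21) and green tissue (18) lists in the 4 genotypes, with circles for replicate 1, squares for replicate 2, and an open circle for the library labelled WT replicate 1. Root hair levels were 0.8 and 0.78 in cob-6 and -0.53 and -0.7 in sfr6-3, and cold levels were -0.83 and -0.69 in sfr6-3 and -0.74 and 0.02 in the double mutant.

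The comparison of the double mutant with sfr6-3 gave the effect of cob-6 without full MED16 function and used no WT values in its folds. BCB rose by 1.63 ± 0.18 (adjusted p = 0.00599), EXT1 by 1.58 ± 0.20 (adjusted p = 0.0124) and ICL by 1.85 ± 0.23 (adjusted p = 0.0124). PIP2-4, a plasma membrane aquaporin gene, fell by 1.73 ± 0.22 (adjusted p = 0.0124), the peroxidase gene PER27 fell by 1.07 ± 0.15 (adjusted p = 0.021) and ILA fell by 0.98 ± 0.15 (adjusted p = 0.0461). COB gave -1.29 ± 0.21 (adjusted p = 0.0511), and MED16 0.10 ± 0.24 (adjusted p = 0.885).

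The 17 root hair genes stood higher in the double mutant than in sfr6-3 at a median of 0.60 (0 called in edgeR, 7 higher at unadjusted p below 0.05, 4 by DESeq2, 6 rose adjusted over the list alone, camera adjusted p = 0.00263, and adjusted p = 0.833 with an estimated correlation). PRP1 gave 2.52 ± 0.49 (adjusted p = 0.0781) and RHS13 1.05 ± 0.23 (adjusted p = 0.113). The 16 jasmonate genes had a median of 0.52 (0 called in edgeR, 6 higher at unadjusted p below 0.05, 1 by DESeq2, 1 rose adjusted over the list alone, camera adjusted p = 0.00738, and adjusted p = 0.853 with an estimated correlation), with the storage protein gene VSP1 at 1.58 ± 0.37 (adjusted p = 0.128). The green tissue and root markers stood at medians of 0.11 (camera adjusted p = 0.654) and -0.28 (camera adjusted p = 0.212). The 21 iron genes stood at 0.75 (camera adjusted p = 0.139), and this p was 0.0449 without WT replicate 1 and 0.0344 with WT replicate 1 less the other 7. The 13 flavonoid genes stood at -0.58 (camera adjusted p = 0.191). Their median was -0.85 without double mutant replicate 1 and -0.361 without double mutant replicate 2. It was -0.475 without sfr6-3 replicate 1 and -0.105 without sfr6-3 replicate 2. The root hair value was 0.0812 without double mutant replicate 2, and the jasmonate value 0.157 without double mutant replicate 1.

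In all, 16 genes were called in the double mutant against sfr6-3, 10 higher and 6 lower, with 3075 at an unadjusted p below 0.05 and 499 by DESeq2. The count was 97 without WT replicate 1, where COB fell by 1.29 (adjusted p = 0.00129), and 95 with WT replicate 1 less the other 7, a setting on unique reads, which alone gave 48. It was 107 without WT replicate 2, 3 without sfr6-3 replicate 1 or replicate 2, 450 without double mutant replicate 1 and 3 without double mutant replicate 2.

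The interaction asked whether the effect of cob-6 differed between the backgrounds. BCB fell by 1.27 ± 0.18 with cob-6 in the WT background (adjusted p = 0.0251) and rose by 1.63 ± 0.18 in sfr6-3, an interaction of 2.91 ± 0.26 (adjusted p = 0.00069). ICL gave -0.71 ± 0.23 in WT and 1.85 ± 0.23 in sfr6-3, an interaction of 2.57 ± 0.33 (adjusted p = 0.0138). PSAB, a plastid gene of photosystem I, gave an interaction of 2.48 ± 0.32 (adjusted p = 0.0152). MRD1 gave 6.14 ± 0.71 (adjusted p = 0.00778) and HEI10 3.87 ± 0.4 (adjusted p = 0.00254). The genes COB and MED16 gave 0.21 ± 0.29 and -0.13 ± 0.33.

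The 18 green tissue markers had a median interaction of 0.36, with 18 of 18 positive (0 called in edgeR and 0 by DESeq2, 3 higher at unadjusted p below 0.05, 0 adjusted over the list alone, camera adjusted p = 0.00475, and adjusted p = 0.864 with an estimated correlation). LHCB1.1 gave 1.12 ± 0.35 and LHCB4.1 0.59 ± 0.23, and the camera adjusted p was 0.0764 without double mutant replicate 2. The mean centred log2 CPM of the green list was 0.1 and 0.27 in WT and -0.32 and 0.01 in cob-6. It was -0.19 and 0.12 in sfr6-3 and -0.1 and 0.11 in the double mutant. Replicates thus lay well apart, and the 18 genes are not independent observations. Other lists had no planned call for the interaction but passed in some settings. The root hair median was -0.12 (camera adjusted p = 0.0956), -0.41 without WT replicate 1 (camera adjusted p = 0.001), -0.26 without double mutant replicate 2 (camera adjusted p = 0.0474) and -0.2 with WT replicate 1 less the other 7 (camera adjusted p = 0.0358). Root markers went from 0.17 (camera adjusted p = 0.121) to 0.42 without WT replicate 1 (camera adjusted p = 0.0308). The flavonoid median was -0.42 (camera adjusted p = 0.158). With a library left out it ran from -0.87 without double mutant replicate 1 to -0.179 without sfr6-3 replicate 2. The abscisic acid genes went from 0.27 (camera adjusted p = 0.63) to 0.29 without double mutant replicate 1. The interaction test called 11 genes, 9 higher and 2 lower, with 1942 at an unadjusted p below 0.05 and 88 by DESeq2. Unique reads alone gave 4 calls, with MRD1 at 4.38 ± 0.77 (adjusted p = 0.125) and HEI10 at 2.24 ± 0.65 (adjusted p = 0.396). With WT replicate 1 less the other 7, which is also on unique reads, the count was 5, with BCB at 2.87 (adjusted p = 0.000265), ICL at 2.22 (adjusted p = 0.0017) and PSAB at 2.42 (adjusted p = 0.026), while MRD1 was at 4.30 (adjusted p = 0.156) and HEI10 at 2.08 (adjusted p = 0.422). The count was 22 without WT replicate 2, 7 without cob-6 replicate 2, 4 without sfr6-3 replicate 1 or replicate 2, and 31 without double mutant replicate 1.

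Across all tested genes, the effect of cob-6 in WT and in sfr6-3, measured on different libraries, correlated at r = -0.02 and rho = 0.05, with a covariance of -0.00668. In 20 simulations without effects r ran from -0.03 to 0.02 and the covariance averaged -0.00153. The simulations treated the libraries as separate, whereas WT replicate 1 held at least the summed unique reads of the other 7, so this pair was not free of shared reads. Of the 19 genes called in WT, 2 were called the same way and 2 the opposite way in sfr6-3, and 14 had the same sign. The correlation was 0.08 without WT replicate 1, where 25 of 138 genes were called the same way, 11 higher against 0.106 by chance and 14 lower against 0.168. With WT replicate 1 less the other 7 it was 0.12, with 15 of 88. Over genes with a mean log2 CPM of at least 1 it was 0.17. The overlaps by chance given here and below take every gene as equally likely to be called. Both contrasts come from the same fit with the same dispersions, so the overlap without a shared effect may be larger.

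The effect of sfr6-3 in WT and in cob-6, subject to the same limit, correlated at r = 0.07 and rho = 0.11, with a covariance of 0.0371 beside -0.000384 in simulations without effects. It correlated at r = 0.07 without WT replicate 1, where 75 of 168 genes were called the same way, and at r = 0.2 with WT replicate 1 less the other 7, where 90 of 151 were. Of the 28 genes called in WT, 21 were called the same way in cob-6, 20 of them lower against 0.232 by chance, and 0 passed the interaction test, which called 11 genes in edgeR, 1942 at an unadjusted p below 0.05 and 88 by DESeq2. RD29A, TGG2, EXT1 and EXLB1, the last pair chosen after their values were seen, fell in both, with EXT1 at -1.06 ± 0.19 (adjusted p = 0.0232) in cob-6. In contrast, the changes cob-6 against WT and double mutant against cob-6 share the cob-6 libraries. They correlated at r = -0.49 and rho = -0.39, and simulations without effects gave r from -0.54 to -0.5. The covariance was -0.218 beside a simulated -0.109. Of the 19 genes lower in cob-6, 12 rose in the double mutant against cob-6, where independent lists gave 0.0889. The simulations gave 1 at most, but they called at most 4 genes in the first comparison, and part of that excess may come from the shared libraries. This correlation was -0.26 without WT replicate 1, where 24 of 138 genes were called the opposite way and 7 the same way, and -0.32 with WT replicate 1 less the other 7, where 23 of 88 were called the opposite way and 5 the same way.

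The authors' deposited table compared the double mutant with cob-6 over the same reads. After Benjamini-Hochberg adjustment of its p-values, 159 genes lay below 0.05, 65 higher and 94 lower in the double mutant, and 102 of them were called the same way here and 0 the opposite way. Their signed folds correlated with those here at a Spearman rho of 0.97 across genes. In the authors' deposited table BCB stood at a fold of 4.88, ICL at 5.28, TGG2 at -5.54, CHS at -3.78 and RD29A at -11.6. A further list in the authors' deposited table names 147 genes as misregulated in cob-6 but not in the double mutant, of which 146 were tested here. Of these, 8 were called in cob-6 against WT and 42 without WT replicate 1, 140 passed an unadjusted p of 0.05, and 72 were higher and 74 lower. The median absolute log2 change of the listed genes was 0.86 in cob-6 against WT and 0.34 in the double mutant against WT. The list was chosen on these libraries, so it is not independent evidence of a return towards WT.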

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

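The test of the plastid share was chosen only after the interaction results had been seen. For 11 genes the effect of cob-6 differed between the WT and sfr6-3 backgrounds by the interaction test of edgeR. BCB differed by 2.91 and ICL by 2.57, on reads unique to them. AT2S2, a seed storage protein gene, differed by a fitted 12.54, on levels of 1.14 and 0.852 CPM in WT, 0 and 0.0821 in cob-6, 0 and 0.0374 in sfr6-3, and 3.54 and 6.75 in the double mutant, so the fitted value is no bound. AT1G58235 differed by 1.4 and the mitochondrial ribosomal RNA gene RRN26 by 1.47. AT3G05905 differed by -3.45 and AT5G01210 by -3.29, with 0.947% and 0.41% of their reads unique. Each of these interactions uses WT replicate 1. In unique reads alone 4 genes were called, all among the 11. With the unique reads of the other 7 libraries also taken off WT replicate 1, 5 were called, 4 of them among the 11, so the lower count is not tied to that library. Without sfr6-3 replicate 1 or replicate 2 the count was 4, where ICL stood at 2.72 (adjusted p = 0.0921) and 2.42 (adjusted p = 0.131).

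MRD1 and HEI10, which overlap, differed by 6.14 and 3.87 and were both low in cob-6. In unique reads HEI10 changed by -0.82 ± 0.47 in cob-6 against WT (adjusted p = 0.999), so reads of MRD1 counted for HEI10 may account for the fall of HEI10. For the converse, reads of HEI10 counted for MRD1, MRD1 stood at -3.36 ± 0.59 in unique reads (adjusted p = 0.0603), a large change that missed the threshold. Its unique reads were 13 and 5 in cob-6, and 761 and 126 in WT. They were 50 and 53 in sfr6-3, and 88 and 168 in the double mutant. In unique reads MRD1 rose by 3.48 ± 0.59 in the double mutant against cob-6 (adjusted p = 0.0116). These values argue against the converse for MRD1. With the reads of the other 7 libraries taken off WT replicate 1, MRD1 fell by 3.29 (adjusted p = 0.0301). An effect of the genotype on MRD1 remains open and was not tested. A variant carried along with cob-6 would also be present in the double mutant, where MRD1 stood at 0.12 ± 0.49 against WT in unique reads. That argues against such a variant for MRD1, unless sfr6-3 offset its effect.

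RRN16S.1, the plastid ribosomal RNA gene, and PSAB differed by 2.5 and 2.48. A different share of plastid RNA in the libraries would raise plastid genes alike, and the other 93 tested plastid genes had a median interaction of 0.66 with a bootstrap SE of 0.091, which argues against that share as the whole cause, although 81 of them were positive. Reads shared with other copies do not account for PSAB, which kept 2.48 ± 0.32 in unique reads (adjusted p = 0.0161), whereas RRN16S.1, with 0.126% unique reads, stays open on that point. Without sfr6-3 replicate 1 PSAB was at 2.32 (adjusted p = 0.184). A difference between the genotypes stays open as untested.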

How the results depend on the processing

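Exon reads, and WT replicate 1 less the other 7 libraries, were chosen only after the data were seen, as was the rule by which a change of the correlation counted as a move. Counts are given in the order cob-6 against WT, sfr6-3 against WT, double mutant against cob-6, double mutant against WT, double mutant against sfr6-3, interaction, and the planned test gave 19, 28, 291, 181, 16 and 11. DESeq2 gave 129, 174, 1010, 736, 499 and 88, and no filter on low counts 356, 408, 1314, 1185, 833 and 224. With only the libraries compared the counts were 8 for cob-6 against WT, 59 for the double mutant against WT and 86 against sfr6-3, and this was not run for the interaction, which needs all 8. A test against a 1.5-fold change gave 6, 4, 57, 54 and 5 in the first 5 contrasts, by its construction fewer. Unique reads gave 48 for the double mutant against sfr6-3 and 4 for the interaction. WT replicate 1 less the other 7 gave 88, 151, 748 and 95 in cob-6, sfr6-3 and the double mutant against WT and the double mutant against sfr6-3, and 5 for the interaction. With each library left out in turn the counts ran from 0 to 138, 3 to 168, 68 to 933, 75 to 767, 3 to 450, and 4 to 31, and a lone library was then assumed to vary like the others. Counts within 1.5 times the planned ones came with other size factors, at 19, 23, 291, 181, 17 and 11, and with exon reads, at 18, 19, 270, 176, 13 and 8. Camera with an estimated correlation called 0 lists in place of 33. With a library left out, camera was run only without WT replicate 1 or either double mutant library. Medians of the flavonoid list were taken with each library left out in turn. The correlation of the cob-6 effects in both backgrounds, -0.02, ran from -0.22 to 0.08 with a library left out and was 0.17 over genes with a mean log2 CPM of at least 1, and the 2 genes called the same way in both became 0 to 25. At an adjusted p of 0.01, 40 genes of the authors' table and 4 of their cob-6 list were called here. Of 3644 values of named genes under the alternatives 3129 kept direction and side of the threshold, 277 lost the call, 226 gained it and 12 changed sign, and the cause was not tested. The sign changes are given with the lowest and highest values over the left-out libraries. MED16 in cob-6 against WT ran from -0.01 without WT replicate 1 to 0.49 without WT replicate 2, and COB in sfr6-3 against WT from -0.36 without WT replicate 1 to 0.38 without WT replicate 2. In the double mutant against cob-6, PDF1.1 ran from -5.07 without double mutant replicate 2 to 5.7 without replicate 1, PR3 from -0.09 to 0.53 for the same libraries, and ABCI4 was at -0.01 in exon reads. MED16 in the double mutant against sfr6-3 ran from -0.19 without double mutant replicate 1 to 0.35 without replicate 2, and the COB interaction from -0.2 without WT replicate 2 to 0.53 without WT replicate 1. The MED16 interaction, -0.13, was at 0.06 in exon reads and 0.08 with WT replicate 1 less the other 7, and ran from -0.42 without double mutant replicate 1 to 0.12 without replicate 2, with 0.11 without WT replicate 1 and 0.1 without cob-6 replicate 2.

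With the replicate number as a replicate block the counts were 21, 33, 216, 176, 13 and 8, with a correlation of 0 and 2 genes called the same way. Of the 33 lists called by camera 31 kept their call and 1 was added. In sfr6-3 against WT the pectin list went from 0.047 to 0.0727 and the cell division list from 0.0376 to 0.0509, and in the double mutant against WT the jasmonate and ethylene defence branch from 0.0584 to 0.014. Same-numbered libraries deviated together at correlations of -0.07 to 0.05, so no deviation shared by number was seen across genes. That cannot exclude samples handled together by number, and the correlations with WT rest on WT replicate 1, which was not independent. At these depths and 2 libraries per genotype, 46 of 100 genes changed 2-fold were recovered in simulation for cob-6 against WT, and depth was not varied there. That simulation drew WT replicate 1 as an independent library, which it was not. Levels under 0.0795 to 0.125 CPM lay below the 3-read floor of the 7 shallower libraries.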

Other observations

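The aquaporin and peroxidase families, the set of genes read almost only in 1 mutant library and the comparison of WT replicate 1 with an ordinary wild-type library were chosen only after the results had been seen. Among 30 aquaporin genes, whose products carry water across the plasma membrane and tonoplast, 3 fell in the double mutant against WT: TIP2-3 at -4.72 ± 0.61, TIP2-2 at -2.16 ± 0.31 and PIP2-4 at -1.14 ± 0.22 on the log2 scale. The median of the family was -0.18, and p-values of set tests on either family are left out because called members had prompted the choice. In cob-6 against WT their median was -0.24, 0 fell in edgeR, 11 were lower at unadjusted p below 0.05, DESeq2 called 5, and 9 fell without WT replicate 1. The count of aquaporin genes that fell in the double mutant against WT was 9 without WT replicate 1.

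Among 66 class III peroxidase genes, which act in the cell wall, 50 stood lower in sfr6-3 than in WT, at a median of -0.32, and PER21 and PER34 fell, or 4 genes without WT replicate 1. In the double mutant against cob-6, 3 rose and 5 fell, and without WT replicate 1 it was 3 and 8. In cob-6 against WT PER23 and PER27 fell and 0 rose in edgeR, 14 were higher and 12 lower at unadjusted p below 0.05, and DESeq2 called 6 higher and 2 lower. Without WT replicate 1, 5 rose and 4 fell there. In the double mutant against WT 3 fell, and without WT replicate 1 it was 9 that fell and 4 that rose.

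Lists without a camera call in any contrast of the planned test had lowest adjusted p-values of 0.47 for COBRA-like genes, 0.273 for lignin, 0.224 for expansins, 0.252 for salicylic acid defence, 0.212 for the pattern-triggered response, 0.0539 for the circadian clock, 0.126 for abscisic acid and dehydration, and 0.612 for Mediator subunits other than MED16. In sfr6-3 against WT the clock list passed without WT replicate 1, at 0.035, and the abscisic acid list without WT replicate 1 or double mutant replicate 1, at 0.0449 and 0.00898, each with camera, lower. In the planned test each list in this paragraph had 0 calls over all genes in edgeR, except for EXLB1 among the expansins and RVE1 in the clock. Fry's test for changes in either direction gave salicylic acid defence an adjusted p of 6.62e-05 in sfr6-3 against WT and in the double mutant against cob-6. Its lowest values were 0.00447 for expansins and 0.0284 for COBRA-like genes, both in the double mutant against cob-6. For the clock it was 0.0396, in the double mutant against sfr6-3. The Mediator list includes the locus listed as MED2 that is also named MED32.

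The library labelled WT replicate 1 lay close to the mean of the other 7 libraries, with a spread of 0.105 around it where those libraries had 0.274 to 0.462. Copies of the other libraries' counts added into it may account for this, since only 0.552% of tested genes had fewer total reads there than in the other 7 together, and the same held for 0 genes in unique reads. Greater depth is argued against by a spread of 0.129 after thinning to the depth of WT replicate 2, where the lowest of the others was 0.271. An ordinary wild-type library is argued against by the median CPM ratio of 0.127 for 15 genes read almost only in double mutant replicate 2, beside 0.116 if WT replicate 1 held all reads of that library. The least number of genes for that last test was lowered from 20 to 10 after 15 had been counted, no biological explanation was tested, and what else the library holds is not known.

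A hypothesis of delayed use of seed reserves in the double mutant was tested on 15 other seed-reserve genes, of which 12 were tested. Their median change against sfr6-3 was a fitted 6.66, or 4.38 with libraries at 0 set to the floor of 3 reads, with 0 calls in edgeR over all genes and 7 rises adjusted over the list alone (camera p = 0.00253, and p = 0.242 with an estimated correlation). The storage protein gene CRA1 stood at 27 CPM in double mutant replicate 2 and at 0.117 CPM in replicate 1, so 1 library decides the values. Against WT the 12 genes had a median of 1.72, with 0 calls in edgeR over all genes and 0 rises adjusted over the list alone (camera p = 0.738, lower, and p = 0.887 with an estimated correlation). Against sfr6-3 the reserve-use genes MLS, PCKA and SDP1 stood at 0 ± 0.24, 0.1 ± 0.14 and -0.13 ± 0.18. The hypothesis stays open.

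A second hypothesis, that variants linked to the mutated loci account for calls in the double mutant against WT, was tested by position. Within 2 Mb of COB or MED16, 11 of 1293 genes were called, against 168 of 20089 elsewhere, an odds ratio of 1.02 (one-sided Fisher's exact p = 0.523). An odds ratio this near 1 neither shows linkage nor excludes it for single genes.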
